A study of Mus musculus with 101 samples.

How the data were processed

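Genomic DNA of 98 mouse mammary tumours and 3 spleens was sequenced at low coverage, per the labels. Each sample has a column in each of the 3 deposited matrices, which hold 43513 gene symbols. Per the labels' protocols, reads were aligned with BWA, counted in bins of 20 kb, corrected for GC content by a smooth fit and then for mappability by a linear model. Per the submitters' processing notes the tools were cutadapt 2.5, BWA 0.7.17, SAMtools 1.10 and Picard, with genome build mm10. The protocol text names a human build, and the mouse build of the processing notes was used here for positions.

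The deposited log2 ratios and log2 segment values were made by the authors from the corrected bin counts, per the labels, and the segment values are the same ratios after segmentation. The deposited copy score is a whole number per gene with 2 as the neutral state, made by the authors, and it equalled 2 times 2 to the power of the segment value, rounded, in 99.9919% of cells. From this rounding a gain call needs a segment value of at least 0.32 and a loss call one of at most -0.42. The segmentation method, the reference of the ratios and the mapping from bins to genes are not given in the sources used here. Read depth per sample is unknown. The noise of neighbouring log2 ratios, which bounds the precision of a gene value, was 0.06 to 0.14 in tumours.

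Tumours were grouped by the genotype in the labels, and by histology and library series within it. The labels do not say which tumours came from separate animals, apart from tumour numbers in the titles, so p-values measure the spread between samples and nothing beyond it. The tumour titled KB1P 47 carries the name of the other model in its description and was kept with its genotype label, as were 10 tumours titled KB1PM. Positions came from a gene table of GRCm38.p6, which placed 32661 symbols directly and 30 by an older symbol, while 10822 stayed without a position and entered only the tests per gene.

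The altered share is the percent of genes with a call other than 2. Breakpoints are changes of segment value between neighbouring placed genes of a chromosome. Large-scale transitions were counted after removal of segments under 3 Mb and joining of segments within 0.1 of each other, between segments of at least 10 Mb. High-level gain was a segment value of at least 1 and deep loss one of at most -1. Means were compared over the 6 genotype pairs by two-sided permutation tests with 100000 resamples, or by exact enumeration where a group had under 10 tumours, with Benjamini-Hochberg adjustment.

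Segment values per gene were compared with limma 3.58.1 in R 4.3.3, as 5 contrasts of group means with moderated variances and adjustment over 43513 genes. The same model compared sarcomatoid tumours with carcinosarcomas within KB1(L1363P)P. Neighbouring genes share segments and are not independent, so calls were also merged into regions. Gain and loss frequencies of listed genes were compared by Fisher's exact test. Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and version 1.17.8 of data.table.

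The tests, the gene lists and the naming rule were chosen before the data were examined. The lists were engineered genes (3 measured), amplification targets (38 of 40), tumour suppressors (29 of 30), genes of homologous recombination and PARP inhibitor response (34 of 35) and drug transporters (2 of 3). Akt1, Aurka, Cdkn2b, Shld3 and Abcb1a were absent from the tables. From each list the text names every engineered gene, and otherwise up to 8 called genes with the largest difference per comparison, or the 2 with the smallest p where none was called. It further names the 6 regions with the largest mean difference on different chromosomes, the most often gained and lost genes per genotype on 3 chromosomes each, and listed genes at high-level gain or deep loss in at least 2 tumours. Gene functions in the text are general knowledge and were not taken from the data.

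The methods were tested on simulated data. With genotype labels shuffled and genes shifted by 0.25, limma recovered 7%, 19% and 22% of them against KP, KB1P and KB2P; with shifts of 0.5 it recovered 82%, 94% and 92%, and it called 0 other genes. Fisher's exact test recovered 80% of genes given a gain in 70% of the tumours of a group and 99.5% at 90%. The permutation test passed in 2 of 40 splits without a difference and in 32 of 40 with 20 points added. All 48 planted breakpoints and all 3 planted large-scale transitions were counted.

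Alternatives planned beforehand covered histology, library series, noise, thresholds, scaling, sex chromosomes, uncertain labels and single tumours. Chosen after the data were seen were large-scale transitions in adenocarcinomas, a threshold of 0.1, library series 5490, fits with only 2 genotypes, removal of 1 of 2 near-identical KB2P profiles, Fisher's exact test between histologies, breakpoints and the level of chromosome 12 by histology, summaries of the called genes in the histology settings, and the tests of high-level gain at Yap1 and Met by histology. The spleens stayed out of every test and gave the background. The RNA sequencing named in the study's design was not used here.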

Results

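Copy-number profiles from low-coverage sequencing of genomic DNA were analysed for 98 mouse mammary tumours and 3 spleens. The tumours came from 4 genotypes: KP (n = 18), KB1P (n = 31), KB1(L1363P)P (n = 24) and KB2P (n = 25). In the usual naming of these conditional mouse models, KP tumours have lost the tumour suppressor Trp53, KB1P tumours Brca1 and Trp53, and KB2P tumours Brca2 and Trp53. KB1(L1363P)P tumours carry a Brca1 missense variant in the coiled-coil domain, the part of the protein that binds Palb2 during homologous recombination. The study asked how tumours with this variant, from different histology classes, compare with those of the other models.

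Histology differed sharply between the genotypes. Of the KB1(L1363P)P tumours, 12 were sarcomatoid, 9 were carcinosarcomas and 3 were adenocarcinomas. KP held 10 sarcomatoid tumours, 2 carcinosarcomas and 6 adenocarcinomas, whereas 29 of the 31 KB1P tumours and all 25 KB2P tumours were adenocarcinomas. Libraries came in 9 series. Series 5289 held 20 KB1(L1363P)P, 10 KB1P and 3 KP tumours and the 3 spleens, and series 5490 held 4 KB1(L1363P)P and 5 KP tumours. The 10 sarcomatoid KP tumours filled series 5750, and KB2P shared no series with another genotype, so that for KB2P library series and genotype cannot be told apart. Each sample had a log2 ratio, a segmented log2 ratio and a copy call for 43513 gene symbols. The depth behind these values is unknown. The noise of the log2 ratios between neighbouring genes had a median of 0.08 in tumours and was 0.05 at most in the spleens. In the spleens no gene was called altered and no segment value exceeded 0.01 in size. The labels do not say which tumours came from separate animals, so p-values measure the spread between these tumours.

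KB1(L1363P)P tumours carried few called copy-number changes and resembled KP tumours in this respect, while KB1P and KB2P tumours carried many. The share of genes with a call other than 2 copies was 7.02% ± 9.71 (SD, n = 24) in KB1(L1363P)P, 7.72% ± 9.95 (SD, n = 18) in KP, 36.4% ± 18.2 (SD, n = 31) in KB1P and 37.0% ± 14.3 (SD, n = 25) in KB2P. Losses made up 4.94% of genes and gains 2.08% in KB1(L1363P)P, against 18.3% and 18.2% in KB1P and 19.1% and 17.9% in KB2P. In the 3 spleens the share was 0%. Calls need a fixed amplitude, and smaller shifts do not enter this share. Beyond a segment value of 0.1 in size the share ran from 9.94% to 73.0% over KB1(L1363P)P tumours and from 16.0% to 89.7% in KP. In KB1P it ran from 5.63% to 78.2% and in KB2P from 21.4% to 76.5%. Genotypes were not tested at this threshold, which was chosen after the data were seen. The plot of altered shares shows the tumours by genotype and histology.

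The altered share of KB1(L1363P)P was lower than that of KB1P by -29.4 points and lower than that of KB2P by -29.9 points. It differed from KP by -0.705 points (permutation adjusted p = 0.896). KB1P and KB2P exceeded KP by 28.7 and 29.2 points and differed from each other by -0.553 points (adjusted p = 0.896). For the 4 large differences the two-sided permutation p was 2.0e-05, the smallest that 100000 resamples can give, and the adjusted p was 3.0e-05 over the 6 pairs. Within library series 5289 the difference between KB1(L1363P)P and KB1P was -20.2 points (permutation adjusted p = 0.00570, n = 20 and 10). There KB1P exceeded KP by 13.7 points (exact permutation adjusted p = 0.288, n = 10 and 3), and KB1(L1363P)P differed from KP by -6.42 points (exact permutation adjusted p = 0.288). Within library series 5490, a setting chosen after the data were seen, KB1(L1363P)P differed from KP by -8.23 points (exact permutation p = 0.286, n = 4 and 5).

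The genotype difference was smaller among adenocarcinomas. There the share was 23.6% ± 18.2 (SD, n = 3) in KB1(L1363P)P, with single values of 44.6%, 14.5% and 11.8%, against 16.4% ± 10.7 (SD, n = 6) in KP, 38.7% ± 16.4 (SD, n = 29) in KB1P and 37.0% ± 14.3 (SD, n = 25) in KB2P. The adenocarcinoma differences of -15.1 points from KB1P and -13.3 points from KB2P did not pass the exact permutation test (adjusted p = 0.237 for both). Without the tumour at 44.6%, replicate 7, they were -25.6 and -23.8 points (exact permutation adjusted p = 0.0194 and 0.0171). In library series 5289 the adenocarcinoma means were 29.6% for KB1(L1363P)P (n = 2), 32.4% for KB1P (n = 8) and 11.9% for KP (n = 2). KB1P and KB2P adenocarcinomas exceeded KP adenocarcinomas by 22.4 and 20.6 points (exact permutation adjusted p = 0.00452 for both). Among sarcomatoid tumours, KB1(L1363P)P held 2.37% ± 3.49 (SD, n = 12) and KP 0.815% ± 1.83 (SD, n = 10), a difference of 1.56 points (permutation p = 0.216).

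**Figure D1:**
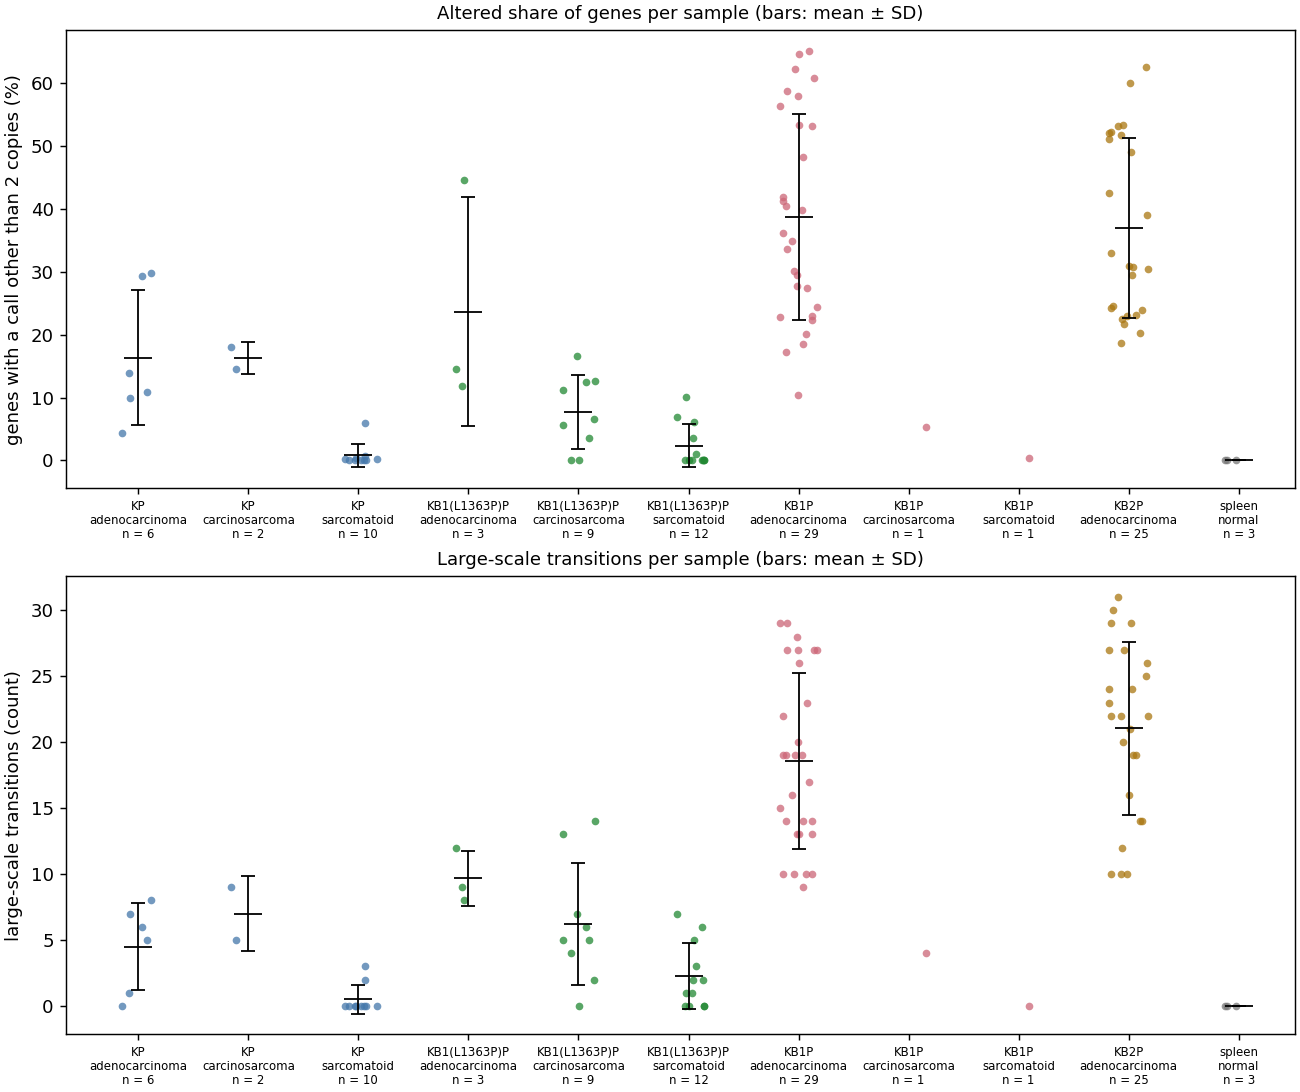
Altered share of genes in percent (top) and number of large-scale transitions (bottom) per sample, by genotype and histology. Points are samples and bars mean ± SD. The spleens sit at 0, the sarcomatoid KB1(L1363P)P tumours average 2.37% altered genes, and the KB1P adenocarcinomas average 38.7%.

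Breakpoints followed the same order of genotypes. A tumour held 34.6 ± 29.4 (SD, n = 24) changes of segment value between neighbouring genes in KB1(L1363P)P, 43.3 ± 52.0 (SD, n = 18) in KP, 144 ± 92.2 (SD, n = 31) in KB1P and 190 ± 90.1 (SD, n = 25) in KB2P. KB1(L1363P)P had fewer than KB1P by -109 and fewer than KB2P by -155 (permutation adjusted p = 4.0e-05 for both), and differed from KP by -8.71 (adjusted p = 0.504). KB1P and KB2P exceeded KP by 100.5 and 146 (permutation adjusted p = 1.2e-04 and 4.0e-05). KB1P differed from KB2P by -45.9 (permutation adjusted p = 0.0821), and by -73.0 (adjusted p = 0.00655) when 10 tumours titled KB1PM and 1 with conflicting labels were left out. Among adenocarcinomas KB1(L1363P)P differed from KB1P by -67.9 (exact permutation adjusted p = 0.261, n = 3 and 29) and KB1P from KP by 69.0 (adjusted p = 0.154, n = 29 and 6), and neither passed; KB1(L1363P)P differed there from KB2P by -106 (adjusted p = 0.0385), a difference that did not pass without any 1 of the 3 tumours, and KB2P from KP by 107 (adjusted p = 0.0302). In library series 5289 KB1(L1363P)P differed from KB1P by -52.4 (permutation adjusted p = 0.0104), and KB1P from KP by 35.1 (exact permutation adjusted p = 0.483, n = 10 and 3).

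Large-scale transitions, the breakpoints between neighbouring segments of at least 10 Mb that are widely used as a mark of defective homologous recombination, were also frequent in KB1P and KB2P. Their number was 4.67 ± 4.25 (SD, n = 24) in KB1(L1363P)P, 2.56 ± 3.22 (SD, n = 18) in KP, 17.5 ± 7.67 (SD, n = 31) in KB1P and 21.0 ± 6.53 (SD, n = 25) in KB2P. KB1(L1363P)P differed from KP by 2.11 (permutation adjusted p = 0.0916), from KB1P by -12.8 and from KB2P by -16.4 (adjusted p = 3.0e-05 for both). In adenocarcinomas alone, a setting chosen after the data were seen, the means were 9.67 ± 2.08 (SD, n = 3) in KB1(L1363P)P, 4.50 ± 3.27 (SD, n = 6) in KP, 18.6 ± 6.66 (SD, n = 29) in KB1P and 21.0 in KB2P. The KB1(L1363P)P adenocarcinomas thus lay between KP and KB1P. The difference of 5.17 from KP did not pass (exact permutation adjusted p = 0.0571), and those of -8.92 from KB1P and -11.4 from KB2P did (exact permutation adjusted p = 0.0200 and 0.0134). Both depended on single tumours: they passed without replicate 19 (adjusted p = 0.0129 for both), but without replicate 7 the adjusted p was 0.0731 against both KB1P and KB2P, and without replicate 21 it was 0.103 against both.

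Within KB1(L1363P)P the sarcomatoid tumours carried the fewest called changes. The altered share was 2.37% ± 3.49 (SD, n = 12) in sarcomatoid tumours, 7.67% ± 5.91 (SD, n = 9) in carcinosarcomas and 23.6% ± 18.2 (SD, n = 3) in adenocarcinomas. Chromosome 12 had the largest lost share of any chromosome in this genotype, 37.9% of its genes on average. The mean segment value of that chromosome was -0.22 ± 0.14 (SD, n = 12) in sarcomatoid tumours, -0.57 ± 0.25 (SD, n = 9) in carcinosarcomas and -0.55 ± 0.21 (SD, n = 3) in adenocarcinomas. KP tumours showed a like pattern, with -0.19 ± 0.14 (SD, n = 10) in sarcomatoid tumours and -0.55 ± 0.21 (SD, n = 6) in adenocarcinomas. The altered share of sarcomatoid tumours differed from that of carcinosarcomas by -5.29 points (two-sided exact permutation p = 0.0231), and by -4.24 points within library series 5289 (exact permutation p = 0.122). The direction turned with lower thresholds: the share of genes with a segment value beyond 0.2 in size was 18.4% in sarcomatoid tumours and 14.9% in carcinosarcomas (difference 3.56 points, which did not pass the exact permutation test), and beyond 0.1 the difference was 19.4 points (exact permutation p = 0.00265). Sarcomatoid tumours had fewer breakpoints than carcinosarcomas, 16.5 ± 12.7 (SD, n = 12) against 42.3 ± 25.6 (SD, n = 9). The exact permutation test, chosen after the data were seen, gave an adjusted p of 0.0117 over 4 histology pairs. All these sarcomatoid tumours were in library series 5289. Carcinosarcoma replicates 22, 23 and 24, of series 5490, had 85, 56 and 41 breakpoints, and the carcinosarcomas of series 5289 had 14 to 75. Breakpoints by histology were not tested within a series.

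KB1(L1363P)P and KP tumours could not be told apart at the level of single genes. Both had high-level gain of the chromosome 9 locus of Yap1, a transcriptional coactivator of the Hippo pathway, with gain calls in 13 of 24 and 12 of 18 tumours. Gain of Met, the receptor of hepatocyte growth factor, was called in 7 of 24 and 5 of 18 tumours. No gene of the 43513 tested passed limma at an adjusted p under 0.05; the smallest adjusted p was 0.809, 15 genes had an unadjusted p under 0.05, and Fisher's exact test on the calls found 0 genes. With only these 2 genotypes in the limma fit, 0 genes were called and 362 had an unadjusted p under 0.05. Both counts are far below a share of 0.05 of the genes tested, so these fits are no evidence that the 2 genotypes are alike. In sarcomatoid tumours alone 1226 genes had an unadjusted p under 0.05, and in adenocarcinomas alone 2173, with 0 called in each. Within library series 5289, with 3 KP tumours, limma called Mdfic, a regulator of transcription factors upstream of Met, and the predicted genes Gm43924 and Gm43990, all at -2.82 (SE 0.44, limma adjusted p = 0.00277). In this series the gained interval around Met took in Mdfic in KP replicates 1 and 3, of 3 KP tumours. It did so in KB1(L1363P)P replicates 5 and 16, of 20 tumours. The 3 genes have the same values and were named after their values were seen.

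None of the 5 gene lists held a called gene in this comparison, over all genes tested or adjusted over the list alone. Among 38 measured amplification targets the smallest p-values belonged to Cul4a, a ubiquitin ligase scaffold, with a difference of -0.28 (SE 0.18) and gain calls in 0 of 24 against 3 of 18 tumours, and Pvt1, the non-coding neighbour of Myc, with 0.23 (SE 0.15) and gain calls in 4 of 24 against 0 of 18. Among 29 tumour suppressors they were Ing1, a chromatin regulator, at -0.16 (SE 0.13) and Map2k4, a stress-signalling kinase, at -0.08 (SE 0.08). Among 34 genes of homologous recombination and PARP inhibitor response they were the checkpoint kinase Chek1 at 0.09 (SE 0.10) and Rif1, which limits DNA end resection, at -0.06 (SE 0.06). The drug efflux transporters Abcg2 and Abcb1b differed by -0.09 (SE 0.09) and -0.04 (SE 0.09). None of the 212 tests of gain and loss frequency over the 106 measured listed genes passed. In simulated data with groups of these sizes, a shift of 0.25 was recovered for 7% of shifted genes and a shift of 0.5 for 82%. The labels there were shuffled over the tumours of all 4 genotypes, so recovery between KB1(L1363P)P and KP tumours themselves was not simulated. Small differences of level could have been missed.

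Over all histologies, KB1(L1363P)P differed from KB1P through high-level gain at Yap1 and Met and through fewer of the broad gains and losses seen in KB1P. The segment value of Yap1 was 2.18 ± 2.31 (SD, n = 24) in KB1(L1363P)P and 0.34 ± 0.94 (SD, n = 31) in KB1P, and that of Met 1.30 ± 2.10 (SD, n = 24) and 0.19 ± 0.24 (SD, n = 31). On chromosome 6, gained broadly in KB1P at a mean segment value of 0.33 ± 0.23 (SD, n = 31) against 0.04 ± 0.12 (SD, n = 24), 1276 of 1798 placed genes were lower in KB1(L1363P)P. On chromosomes 8, 10 and 16, which had losses in KB1P, 280, 180 and 221 genes were higher, and on chromosome 8 another 106 were lower. The 3 KB1(L1363P)P adenocarcinomas also had losses on chromosomes 8 and 10, where 62.1% and 36.0% of genes were lost on average, against 43.5% and 35.7% in KB1P adenocarcinomas. The mean segment values there were -0.52 ± 0.41 and -0.36 ± 0.14 (SD, n = 3) against -0.16 ± 0.30 and -0.07 ± 0.28 (SD, n = 29), a comparison that was not tested. In KB1(L1363P)P carcinosarcomas the lost shares were 5.41% and 4.79%, and in sarcomatoid tumours 0% on both chromosomes. On chromosome 16 the KB1(L1363P)P adenocarcinomas had lost 2.14% of genes, against 33.4% in KB1P adenocarcinomas. Limma called 5886 genes, 1160 higher and 4726 lower, in 75 regions on 12 chromosomes. With each tumour centred on its autosomal median the split was 2395 higher and 3757 lower, and without the KB1PM titles and the conflicting label it was 2087 higher and 2747 lower.

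Of 38 measured amplification targets, 8 were called in this comparison, 5 higher and 3 lower, and 8 adjusted over the list alone. Yap1 and its neighbours Birc2 and Birc3, inhibitors of apoptosis on the same segment, were higher by 1.84 (SE 0.41, adjusted p = 0.000917), and Met by 1.11 (SE 0.35, adjusted p = 0.0240). Cdk4, a cell-cycle kinase, was higher by 0.25, with loss calls in 2 of 24 against 17 of 31 tumours. Ccnd2, a D-type cyclin, fell by 0.32, Mdm4, a negative regulator of Trp53, by 0.20, and Rad21, a cohesin subunit gained in 17 of 31 KB1P tumours, by 0.17. Of 29 tumour suppressors, 5 were called and 6 adjusted over the list alone: the forkhead factor Foxp1 at -0.44 (SE 0.08, adjusted p = 1.06e-05), Vhl of the hypoxia-factor ubiquitin ligase at -0.40, the kinase inhibitor Cdkn1b at -0.33, Ing1 at -0.31 and the adhesion protein gene Cdh1 at 0.23. Loss of Cdh1 was called in 3 of 24 against 17 of 31 tumours.

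Of 34 homologous recombination and PARP inhibitor genes, 5 were called, all lower, and 5 adjusted over the list alone. They were Fancd2, which acts in crosslink repair, at -0.40 (SE 0.07, adjusted p = 2.26e-05), the resection nuclease gene Mre11a at -0.39, the annealing factor Rad52 at -0.33, Bard1, the partner of Brca1, at -0.33, and Chek1 at -0.29. In KB1P gain of Fancd2 was called in 14 of 31 and of Bard1 in 11 of 31 tumours. Abcg2, 1 of 2 measured drug transporters, was lower by -0.39, with gain calls in 1 of 24 against 17 of 31 tumours. Beyond the lists, the regions with the largest mean difference were led by Tmem123 on chromosome 9 (6928550 to 9619784, mean 1.66), Met on chromosome 6 (16777524 to 19319400, 0.96), Cdk15 on chromosome 1 (57291169 to 75637221, -0.39), the ephrin gene Efnb2 on chromosome 8 (4613170 to 11054541, -0.36), the proteasome gene Psmc1 on chromosome 12 (100079490 to 100725328, -0.30) and the vesicle gene Syngr2 on chromosome 11 (113244851 to 121858571, -0.29). Of 3 engineered genes 0 were called by limma and 1 adjusted over the list alone, Brca2 at -0.18 (unadjusted p = 0.00685). Of 212 tests of gain and loss frequency of listed genes, 34 passed.

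How much of the contrast with KB1P goes with histology was not resolved, except at Yap1. With histology as a covariate limma called 0 genes. The difference at Yap1 fell from 1.84 (SE 0.41) to -0.17 (SE 0.43, adjusted p = 0.882), and that at Foxp1 went from -0.44 (SE 0.08) to -0.32 (SE 0.11, adjusted p = 0.156). Of the 5886 genes called in the main fit 93.2% kept their direction, their median difference in that direction went from 0.29 to 0.20, and the median SE rose from 0.08 to 0.11. Over all genes 4129 had an unadjusted p under 0.05, and the median difference was -0.09, against -0.05 in the main fit. Among adenocarcinomas, with 3 KB1(L1363P)P tumours, limma called 0 genes, with -0.20 (SE 0.38, adjusted p = 0.828) at Yap1. There 89.0% of the 5886 genes kept their direction, with a median of 0.20 and a median SE of 0.20. The summaries over the genes called in the main fit, here and below, were chosen after the data were seen. Those genes were picked by the main fit, and the settings refit the same tumours or a part of them. A kept direction is therefore largely built in and is no evidence that a contrast is independent of histology. Within library series 5289 limma called 4247 genes. Over all tumours of both genotypes Fisher's exact test on the calls found 12730 genes, of which 4757 were among the 5886 of the main fit.

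**Figure D2:**
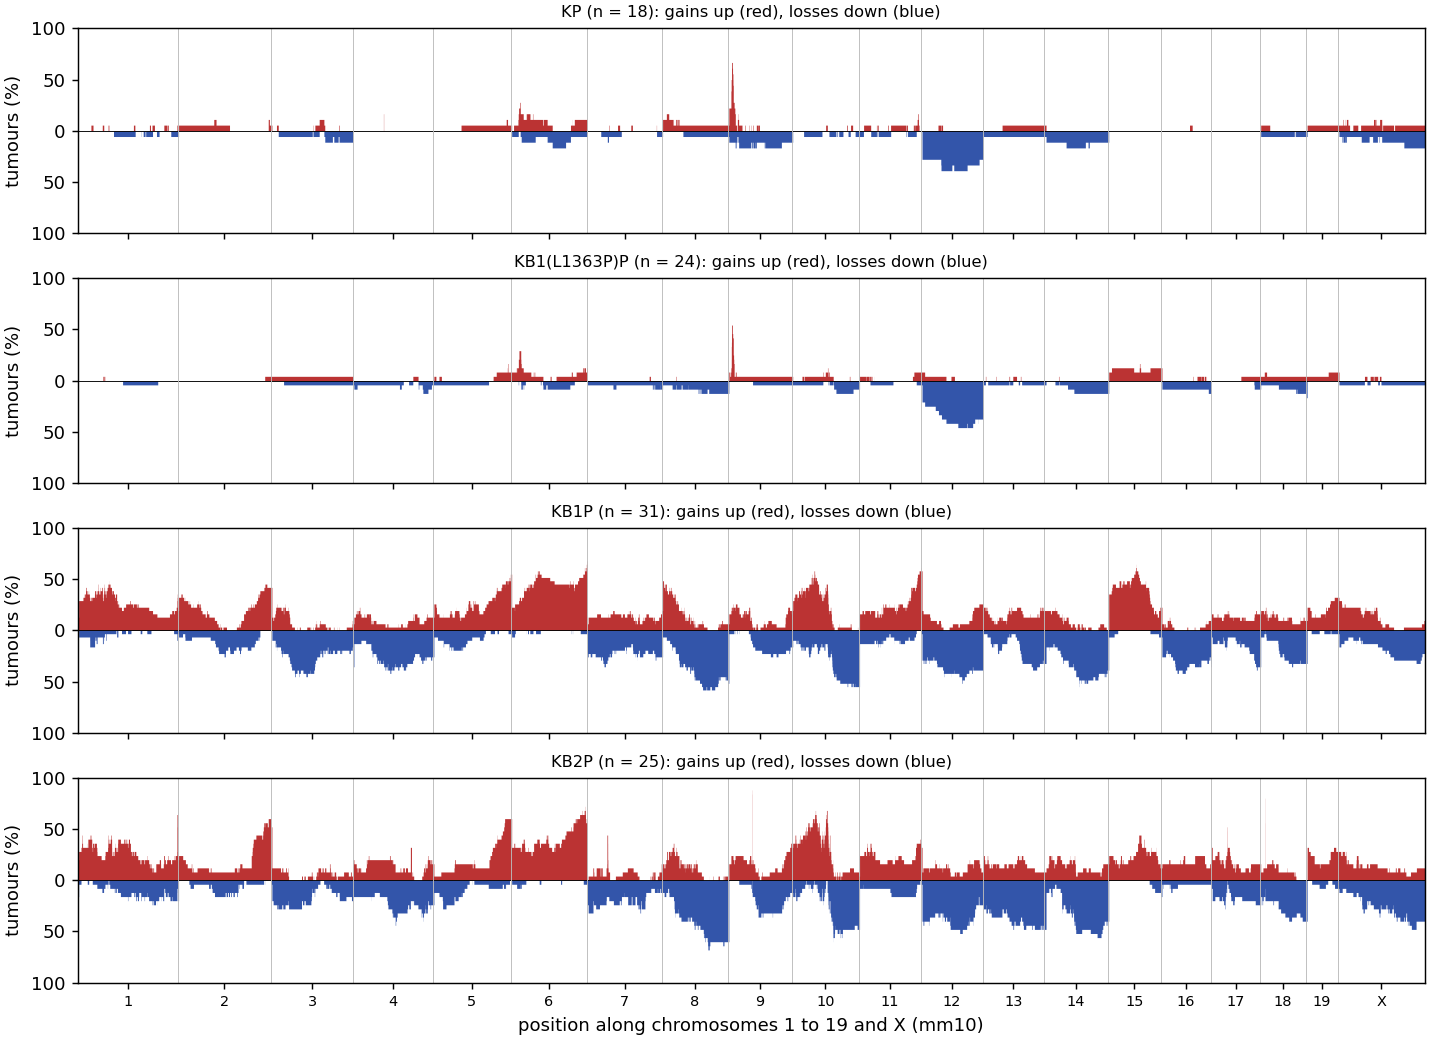
Percent of tumours of each genotype with a gain call (upward) or a loss call (downward) for each placed gene, along chromosomes 1 to X. Gain on chromosome 6 and loss on chromosome 8 recurred in KB1P and KB2P, and loss on chromosome 12 in all 4 genotypes.

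Over all histologies, KB1(L1363P)P differed from KB2P at Yap1 and Met and on several chromosomes. The overlap with the contrast to KB1P, which shares the KB1(L1363P)P tumours, was not tested. Yap1, Birc2 and Birc3 were higher by 1.98 (SE 0.44, adjusted p = 0.00261) and Met by 1.24 (SE 0.37, adjusted p = 0.0153), with KB2P means of 0.21 ± 0.36 and 0.06 ± 0.36 (SD, n = 25). A stretch of chromosome 10 at 41188172 to 49790161 had a mean difference of -0.78. Its leading gene, the pseudogene Rps19-ps11, was gained in 15 of 25 KB2P tumours and 1 of 24 KB1(L1363P)P tumours and differed by -0.93 (SE 0.24, adjusted p = 0.00885). Gain of Thoc1, a gene of messenger RNA export on chromosome 18 (9958180 to 9995484), was called in 20 of 25 against 2 of 24 tumours, a difference of -0.49 (SE 0.09, adjusted p = 0.000347). A step of at least 0.3 over the neighbouring genes was present there in 18 of 25 against 0 of 24 tumours. Limma called 5567 genes, 1469 higher and 4098 lower, in 70 regions on 15 chromosomes.

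Of 38 amplification targets, 6 were called against KB2P and 6 adjusted over the list alone. Besides the 4 gained genes these were Ccnd2 at -0.36 and the anti-apoptotic Bcl2l1 at -0.26, gained in 11 of 25 KB2P tumours and 0 of 24 KB1(L1363P)P tumours. Of 29 tumour suppressors, 6 were called and 6 adjusted over the list alone: Cdkn1b at -0.41, Cdh1 at 0.32, Keap1, an adaptor of the oxidative stress response, at -0.28, Vhl at -0.28, Foxp1 at -0.26 and the chromatin remodeller Arid1a at 0.22. Of 34 homologous recombination genes, 3 were called and 3 adjusted over the list alone, namely the recombination gene Xrcc3 at -0.49 (SE 0.12, adjusted p = 0.00587), Fancd2 at -0.28 and the Fanconi core gene Fanca at 0.27. Of 3 engineered genes 1 was called and 1 adjusted over the list alone, Brca2 at -0.28 (SE 0.07, adjusted p = 0.00650). Neither transporter passed, with Abcg2 at -0.16 (adjusted p = 0.217) and Abcb1b at 0.03 (adjusted p = 0.832). Further regions were led by the transcription factor gene Klf7 on chromosome 1 (63025755 to 66063379, -0.45) and Glp1r, the receptor of glucagon-like peptide, on chromosome 17 (30592861 to 30952426, -0.39). Of 212 frequency tests 12 passed, among them loss of the kinase Stk11 in 0 of 24 against 13 of 25 tumours. With histology as a covariate limma called 4 genes, all lower: 2900052N01Rik, Gm4791 and Gm47153 at -1.21 and Gm31698 at -0.68. The first 3 had the same values and are not separate results. Gm47153 has no position, and the others lie on chromosome 9. A short step at 2900052N01Rik was present in 24 of 25 KB2P and 0 of 24 KB1(L1363P)P tumours. An inherited variant of the line or a library series effect could not be tested for it. Among adenocarcinomas it called 0 genes, and no library series held both genotypes. With the covariate Yap1 went to -0.18 (SE 0.46, adjusted p = 0.953) and Met to 0.80 (SE 0.47, adjusted p = 0.681). Among adenocarcinomas Met was 0.02 (SE 0.40). Of 16 named genes that kept direction without passing with the covariate, 3 were no smaller than in the main fit. These were Thoc1 at -0.54 (SE 0.14), Xrcc3 at -0.62 (SE 0.17) and Rps19-ps11 at -0.99 (SE 0.35). Of the 5567 genes 94.1% kept their direction with the covariate, at a median of 0.19 against 0.30 and a median SE of 0.12 against 0.09, and 70.5% did so among adenocarcinomas. The 4 genes were named after their values were seen.

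KB1P tumours differed from KP tumours by broad gains and losses and by a rarer gain of Yap1, called in 7 of 31 against 12 of 18 tumours. Chromosome 6 was gained in KB1P, with 1058 genes higher. Parts of chromosomes 1 (620 genes), 9 (381 genes) and 2 (326 genes) were also higher, while chromosomes 8, 10 and 16 held 551, 536 and 336 lower genes. The mean segment value of chromosome 9 was -0.01 in KB1P and -0.13 in KP, so higher values there need not be gains. Yap1, Birc2 and Birc3 were lower by -2.31 (SE 0.45, adjusted p = 0.000140), from 2.65 ± 2.29 (SD, n = 18) in KP to 0.34 ± 0.94 (SD, n = 31). Loss of Mdm2, the ubiquitin ligase for Trp53, was called in 17 of 31 KB1P tumours and 0 of 18 KP tumours, and gain of Myc in 15 of 31 against 0 of 18. Limma called 5872 genes, 3924 higher and 1948 lower, in 69 regions. With each tumour centred on its autosomal median the split was 2539 higher and 2569 lower, and without the KB1PM titles and the conflicting label it was 2502 higher and 2589 lower, so that in neither setting were more genes higher than lower.

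Of 38 amplification targets, 6 were called and 8 adjusted over the list alone: Yap1, Birc2 and Birc3, Mdm2 at -0.37, Cdk4 at -0.31 and Rad21 at 0.20. Of 29 tumour suppressors, 4 were called and 4 adjusted over the list alone, with Foxp1 at 0.46 (SE 0.09, adjusted p = 7.81e-05), Vhl at 0.40, Keap1 at 0.30 and Cdh1 at -0.31. Of 34 homologous recombination genes, 7 were called and 7 adjusted over the list alone. Mre11a at 0.42, Fancd2 at 0.40, Chek1 at 0.38, Rad52 at 0.38 and Bard1 at 0.36 were higher, and Helb, a helicase that restrains resection, at -0.36 and Polq, the polymerase of microhomology end joining, at -0.19 were lower. Abcg2 was higher by 0.30. Of 3 engineered genes 1 was called and 2 adjusted over the list alone, with Brca2 at 0.26 (SE 0.07, adjusted p = 0.0110). The leading regions were those of the pseudogene Cbx3-ps8 on chromosome 9 (6070220 to 9260885, -1.95), the caveolin gene Cav2 beside Met on chromosome 6 (17281185 to 17341328, -1.02), Cdk15 on chromosome 1 (58462771 to 62642284, 0.50), the pseudogene Kifc5c-ps on chromosome 10 (114801726 to 130536024, -0.32), Syngr2 on chromosome 11 (116470816 to 121858571, 0.32) and Nkd1, a regulator of Wnt signalling, on chromosome 8 (79639676 to 111393821, -0.32). Of 212 frequency tests 26 passed. Limma called 435 genes with histology as a covariate, all higher, 450 among adenocarcinomas, 426 higher and 24 lower, and 852 within library series 5289. With the covariate no lower gene was called: Yap1, Birc2 and Birc3 went from -2.31 (SE 0.45) to -0.35 (SE 0.40, adjusted p = 0.766), Mdm2 from -0.37 (SE 0.11) to -0.25 (SE 0.13, adjusted p = 0.483), Cdk4 from -0.31 (SE 0.08) to -0.18 (SE 0.10) and Cdh1 from -0.31 (SE 0.09) to -0.08 (SE 0.10). Foxp1 stayed called at 0.41 (SE 0.10, adjusted p = 0.0134). Of 24 named genes that kept direction without passing with the covariate, 2 were no smaller than in the main fit. These were Rad21 at 0.23 (SE 0.07, adjusted p = 0.0948) and Cav2 at -1.16 (SE 0.40, adjusted p = 0.126). Cav2 was called among adenocarcinomas, at -1.23 (SE 0.29, adjusted p = 0.00835). It lies in the interval gained with Met, which was at high-level gain in 2 of 6 KP adenocarcinomas and 0 KB1P tumours. Among adenocarcinomas Mdm2 was -0.47 (SE 0.19, adjusted p = 0.378), Cdk4 -0.29 (SE 0.14) and Helb -0.42 (SE 0.20), about as large as in the main fit with a larger SE, while Yap1 was -0.27 (SE 0.28) and Cdh1 -0.16 (SE 0.15). Of the 5872 genes, picked by the main fit on the same tumours, 99.9% kept their direction in both settings. Their median of 0.31 and median SE of 0.08 became 0.21 and 0.10 with the covariate, and 0.29 and 0.14 among adenocarcinomas. High-level gain of Yap1 was present in 9 of 10 sarcomatoid and 1 of 6 adenocarcinoma KP tumours.

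KB2P tumours differed from KP tumours at Yap1 and Met and on several chromosomes. Yap1, Birc2 and Birc3 were lower by -2.45 (SE 0.47, adjusted p = 0.00109) and Met by -1.15 (SE 0.40, adjusted p = 0.0428). Chromosome 8 held 758 lower genes, among them Cdh1 at -0.41 (SE 0.09, adjusted p = 0.00131) and Fanca at -0.36, both lost in 15 of 25 against 1 of 18 tumours. Rps19-ps11 on chromosome 10 was higher by 1.06 (SE 0.26, adjusted p = 0.00350), in a stretch with a mean difference of 0.87, and Thoc1 by 0.52 (SE 0.10, adjusted p = 0.00109). Limma called 5226 genes, 3434 higher and 1792 lower, in 73 regions; with each tumour centred on its autosomal median the split was 2552 higher and 2329 lower.

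In KB2P against KP, 5 of 38 amplification targets were called and 5 adjusted over the list alone, the remaining one being Bcl2l1 at 0.24. Of 29 tumour suppressors, 5 were called and 6 adjusted over the list alone: Cdh1, Keap1 at 0.34, Vhl at 0.28, Foxp1 at 0.27 and Smad4, a mediator of transforming growth factor signalling, at -0.27. Of 34 homologous recombination genes, 5 were called and 5 adjusted over the list alone, with Xrcc3 at 0.45, Chek1 at 0.33, Rad52 at 0.28 and Fancd2 at 0.28 higher and Fanca lower. Of 3 engineered genes 1 was called and 1 adjusted over the list alone, Brca2 at 0.36 (SE 0.07, adjusted p = 0.00109). Abcb1b and Abcg2 differed by -0.07 and 0.07, with 0.688 the smaller adjusted p. Further regions were led by Cav1 beside Met (17281185 to 18145944 on chromosome 6, -1.13), the Wnt receptor gene Fzd7 on chromosome 1 (58900449 to 59636417, 0.56) and Atp5mpl, a subunit of the mitochondrial ATP synthase, on chromosome 12 (111159850 to 113004481, 0.44). Of 212 frequency tests 18 passed. Limma called 25 genes with histology as a covariate, all higher, and 23 among adenocarcinomas, 3 higher and 20 lower. With the covariate Yap1, Birc2 and Birc3 went from -2.45 (SE 0.47) to -0.34 (SE 0.43, adjusted p = 0.834), Cdh1 from -0.41 (SE 0.09) to -0.16 (SE 0.11, adjusted p = 0.640) and Fanca from -0.36 (SE 0.10) to -0.12 (SE 0.12), and none was called among adenocarcinomas. Met was -1.24 (SE 0.43, adjusted p = 0.234) with the covariate, not called at a difference no smaller than the main one of -1.15 (SE 0.40), and -1.37 (SE 0.30, adjusted p = 0.0344) among adenocarcinomas. High-level gain of Met was present in 2 of the 6 KP adenocarcinomas and in 0 KB2P tumours. Thoc1 stayed called with the covariate at 0.56 (SE 0.13, adjusted p = 0.0466). Of the 5226 genes 99.8% kept their direction with the covariate and 99.9% among adenocarcinomas. Their median of 0.33 and median SE of 0.09 became 0.22 and 0.11 with the covariate, and 0.29 and 0.15 among adenocarcinomas.

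Within KB1(L1363P)P, sarcomatoid tumours had higher values than carcinosarcomas at Yap1 and along chromosomes 12 and 16. The segment value of Yap1, Birc2 and Birc3 was 3.68 ± 1.77 (SD, n = 12) in sarcomatoid tumours and 0.91 ± 2.03 (SD, n = 9) in carcinosarcomas, a difference of 2.77 (SE 0.75, limma adjusted p = 0.0317). On chromosome 12, 892 genes from 48555059 to 120021242 were higher. On chromosome 16, 1037 genes were higher, and the leading region held the microRNA gene Mir802 at 0.24 (SE 0.06). Limma called 2540 genes, all higher, while a random exchange of the labels among these tumours called 4868. Fisher's exact test on the calls found 0, and limma on each tumour divided by the SD of its segment values called 1270.

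By list, 3 of 38 amplification targets were called in this comparison, the 3 genes of the Yap1 segment, and 3 adjusted over the list alone. Of 34 homologous recombination genes, 3 were called and 3 adjusted over the list alone: Rad51b at 0.41 (SE 0.08, adjusted p = 0.00142) and Xrcc3 at 0.39 (SE 0.08, adjusted p = 0.00281), which both act in strand exchange and lie on chromosome 12, and Polq on chromosome 16 at 0.20. Loss of Rad51b was called in 1 of 12 sarcomatoid tumours and 7 of 9 carcinosarcomas. None of the 29 tumour suppressors passed, with Arid1a at 0.11 and Stk11 at -0.15 (adjusted p = 0.201 for both), nor did the transporters Abcb1b at 0.17 (adjusted p = 0.201) and Abcg2 at -0.02 (adjusted p = 0.947).

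Among the listed genes, high-level gain, a segment value of at least 1, was most frequent at Yap1, Birc2 and Birc3. Gain at this locus was concentrated in sarcomatoid tumours. Yap1, Birc2 and Birc3 passed this level in 26 of 98 tumours: 12 of KB1(L1363P)P, 11 of KP, 2 of KB1P and 1 of KB2P. Among KP and KB1(L1363P)P tumours the gain was present in 19 of 22 sarcomatoid tumours and 4 of 20 others, a difference of 66.4 points (two-sided Fisher's exact test, adjusted p = 4.04e-04 over 14 tests). Gain of Met was present in 7 of 11 carcinosarcomas and 5 of 31 other tumours, a difference of 47.5 points (Fisher's exact test, adjusted p = 0.0166). The KB1(L1363P)P carcinosarcomas 54.1 and 54.2, which share a number in their titles, both carried it and were counted as separate tumours. Within KB1(L1363P)P alone the Yap1 difference passed, with 10 of 12 against 2 of 12 tumours (adjusted p = 0.0155), and the Met difference did not, with 5 of 9 against 2 of 15 (adjusted p = 0.0848), nor did that between sarcomatoid tumours and carcinosarcomas at Met (adjusted p = 0.171). These histology tests were chosen after the data were seen. Within library series 5289 the Yap1 gain was present in 10 of 12 against 3 of 11 tumours (exact adjusted p = 0.116 over 12 tests) and the Met gain in 3 of 7 against 3 of 16 (exact adjusted p = 0.546). Both gains were present together in 2 of the 98 tumours.

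The gained interval shared by the 26 tumours ran from 7751672 to 8181112 on chromosome 9 (GRCm38), a length of 0.429 Mb with 10 genes, among them Tmem123, Birc2, Birc3, Yap1, Cfap300 and Cep126. The intervals of single tumours were 1.22 to 14.4 Mb long and had 21 distinct pairs of edges, with a median segment value of 4.44 at Yap1. In the 3 spleens the value at Yap1 was at most 0.00. The interval shared by the 12 tumours with Met gain ran from 17281185 to 18322770 on chromosome 6, a length of 1.04 Mb with 13 genes, among them Cav1, Cav2, Met, Capza2, St7, Wnt2 and Cftr. All 12 had distinct edges, and the median segment value was 4.25.

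**Figure D3:**
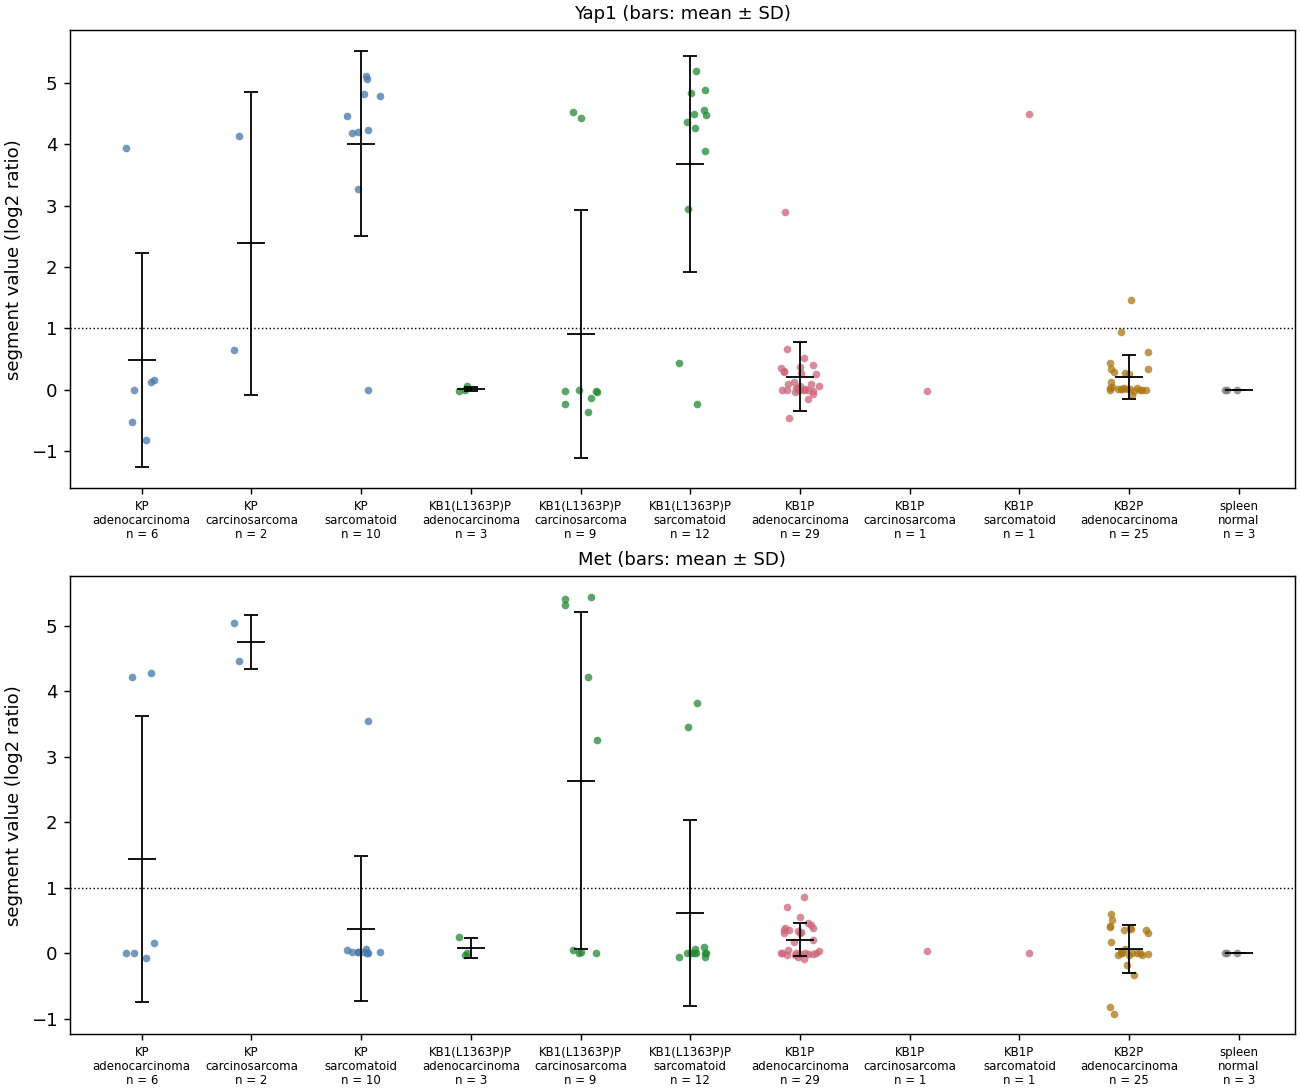
Segment value (log2) at Yap1 and at Met per sample, by genotype and histology. Points are samples, bars mean ± SD, and the dotted line marks the level of 1 for high-level gain. Of 22 sarcomatoid KP and KB1(L1363P)P tumours, 19 lie above it at Yap1.

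**Figure D4:**
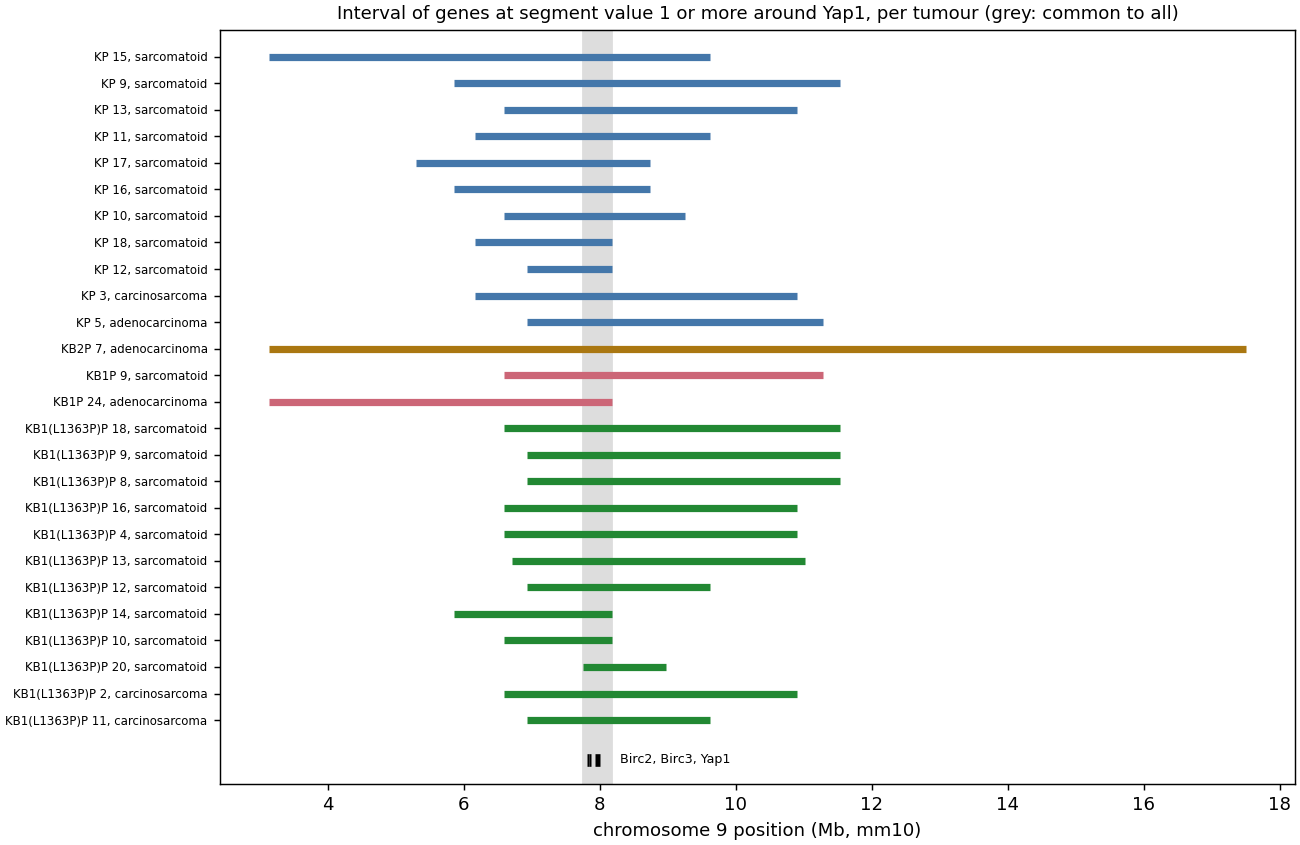
Extent of the gained interval around Yap1 in the 26 tumours with a segment value of at least 1, along chromosome 9 in Mb (GRCm38). Each line is a tumour, coloured by genotype, and the shaded part is the shared interval of 0.429 Mb.

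Other listed genes reached high-level gain more rarely. Cul4a passed in 7 tumours, 4 of KB1P, 2 of KB2P and 1 of KP, and Myc with Pvt1 in 6, 4 of KB2P and 2 of KB1(L1363P)P. Mcl1, an anti-apoptotic gene, passed in 3 tumours, and Pik3ca, a lipid kinase gene, in 3, all KB1P. Ccnd2, the cell-cycle kinase gene Cdk6 and the receptor gene Fgfr1 passed in 2 tumours each. Among suppressors, Rb1 fell to -1 or below in 5 tumours, 3 of KB1P and 2 of KB2P.

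The genes gained or lost most often are given by model, and differences between models in this ranking were not tested. Each named gene stands for all genes of its chromosome at the same count, from 2 genes at 2900052N01Rik to 926 at Mtmr2. In KP and KB1(L1363P)P the most frequent gain lay at Dync2h1 on chromosome 9, in 12 of 18 and 13 of 24 tumours (25 genes at this count in each), followed by chromosome 6 at Cav2 (5 of 18) and Tfec (7 of 24), then Ptbp3 on chromosome 4 (3 of 18) and Cyp3a57 on chromosome 5 (4 of 24). Their most frequent losses were on chromosome 12, at Etv1 in 7 of 18 (482 genes at this count) and Daam1 in 11 of 24 (317 genes), followed by Gcfc2 and Mtmr2 (3 of 18 each) in KP and Eif3s6-ps2 (4 of 24) and Htr1d (3 of 24) in KB1(L1363P)P. KB1P tumours most often gained Ipo8 on chromosome 6 (21 of 31), Dscc1 on chromosome 15 (20 of 31) and Hmga1b on chromosome 11 (19 of 31), and lost Otud4 on chromosome 8 (18 of 31, 226 genes at this count), Otogl on chromosome 10 (17 of 31, 297 genes) and Gm46476 on chromosome 14 (17 of 31). KB2P tumours most often gained 2900052N01Rik on chromosome 9 (22 of 25), Thoc1 on chromosome 18 (20 of 25) and Bcat1 on chromosome 6 (18 of 25), and lost Tox3 on chromosome 8 (17 of 25), Diras1 on chromosome 10 (15 of 25) and Scel on chromosome 14 (14 of 25).

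The engineered genes showed small shifts of log2 ratio. The log2 ratio of Brca1 was 0.01 ± 0.29 (SD, n = 31) in KB1P, -0.04 ± 0.12 (SD, n = 24) in KB1(L1363P)P, -0.05 ± 0.25 (SD, n = 18) in KP and -0.09 ± 0.33 (SD, n = 25) in KB2P, and none of the 6 differences passed (permutation adjusted p between 0.564 and 0.831 over 18 tests). Relative to the median of the 20 nearest genes on each side, Brca1 was lower in KB1P than in KP by -0.08 (permutation adjusted p = 2.70e-04) and than in KB2P by -0.13 (adjusted p = 1.80e-04). On this scale KB1(L1363P)P differed from KB1P by 0.06 (adjusted p = 0.0531), from KB2P by -0.08 (adjusted p = 0.0256) and from KP by -0.03 (adjusted p = 0.323). Brca2 relative to its neighbours was lower in KB2P than in KB1(L1363P)P and KB1P, with differences of 0.08 for each (adjusted p = 1.80e-04 and 2.40e-04), but it did not pass against KP, where Brca2 also lay below its neighbours (-0.10 in KP and -0.13 in KB2P, difference -0.04, adjusted p = 0.0906). As deposited, Brca2 was instead higher in KB1P and KB2P than in KP, by 0.30 and 0.31 (permutation adjusted p = 7.20e-04 and 0.00180). Gain of Brca2 was called in 15 of 31 KB1P, 15 of 25 KB2P, 2 of 24 KB1(L1363P)P and 1 of 18 KP tumours. Trp53, engineered in all 4 genotypes, showed no difference that passed, and its values were -0.10 in KP, -0.07 in KB1P, -0.12 in KB1(L1363P)P and -0.17 in KB2P, against 0.03 in the spleens.

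Tumours that shared a number in their titles were compared over all genes within a pair; genes are not independent replicates. The correlation of log2 ratios was 0.617 for the carcinosarcomas 54.1 and 54.2, 0.150 for 26.1 and 26.2 and 0.117 for 7.1 and 7.2, the last 2 pairs being a sarcomatoid tumour and an adenocarcinoma each. The other 193 pairs of KB1(L1363P)P tumours within a library series had a median of 0.226 and a highest value of 0.764. Among KB2P tumours the profiles of 24 and 26 correlated at 0.933, against a highest value of 0.470 among the other 299 pairs. Their libraries were in different series, their mean segment values differed most on chromosome 6, by 0.12, and they were kept as 2 tumours.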

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

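The altered share within library series 5289 was a planned setting; the other tests of explanations in this part were chosen only after the results were seen. KP sarcomatoid tumour 10 had an altered share of 6.01%, while the next highest of the 10 sarcomatoid KP tumours had 0.722%. The gap made up 0.892 of the range of the group, above the limit of Dixon's test for 10 samples. Of 9 combinations of group and measure tested this way, 1 passed the limit. The altered share changed from adenocarcinoma to sarcomatoid tumours by -21.3 points in KB1(L1363P)P (n = 3 and 12) and -15.6 points in KP (n = 6 and 10). The difference of -5.71 points did not pass (permutation p = 0.559 with 10000 resamples). Genotype labels were exchanged within each histology, which assumes no genotype effect in either. With 3 adenocarcinomas this does not show that the changes are alike.

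Sarcomatoid tumours of KB1(L1363P)P had a lower called share than carcinosarcomas. The calls need a fixed amplitude, so admixed normal cells could lower the share with no difference in the changes themselves. Such dilution can only lower the share beyond a given value, but beyond a segment value of 0.1 the share was higher in sarcomatoid tumours by 19.4 points (exact permutation p = 0.00265), which argues against it as the whole cause. Further changes of low level, such as in subclones, were not tested. A difference between library series cannot be excluded, since within series 5289 the difference was -4.24 points with exact permutation p = 0.122. Breakpoints were lower by -25.8. They count only changes within a chromosome, so a shift of a whole chromosome adds none, and fewer breakpoints need not mean fewer changes. A biological difference in the number of changes is not ruled out by these values.

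High-level gain at Yap1 in sarcomatoid tumours could come from an inherited variant or a mapping fault. The 26 gained intervals had 21 distinct pairs of edges and the 3 spleens lacked the gain, whereas such a cause would give shared edges and a gain in normal tissue. The spleens carry less weight than the edges. All 3 were in series 5289, and the reference of the ratios is unknown. If the spleens served as the reference, a gain in them would not show. A series difference as the whole cause would leave little difference within a series. Within series 5289 the frequency differed by 56.1 of the pooled 66.4 points, in 10 of 12 against 3 of 11 tumours (exact p = 0.0123 unadjusted, 0.116 adjusted over 12 tests). This size does not support a series difference, but with so few tumours it did not pass after adjustment, so the series was not excluded. Selection for the gain in these tumours stays open.

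The short gains at Thoc1 and 2900052N01Rik were steps of at least 0.3 over the neighbouring genes in 18 and 24 of 25 KB2P tumours. Both could be an inherited variant of the line, but 0 spleens of KB2P animals were among the samples. They could also come from the library series, but 0 samples of other genotypes were in those series. The steps were not confined to 1 series. In library series 3196 and 3499 they were present in 14 of 20 and 4 of 5 tumours at Thoc1. At 2900052N01Rik they were present in 19 of 20 and 5 of 5. A step was also present in 1 of 31 KB1P tumours at each gene, and in 0 KP and 0 KB1(L1363P)P tumours. Neither an inherited variant nor an effect common to both series could be tested with these samples.

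Exchanging the labels of the tumours gave, over 100 splits that include the real one, the following counts. For KB1(L1363P)P against KP the real count was 0, which all 100 splits reach by construction, so the splits test nothing there; the highest other count was 31. For KB1(L1363P)P against KB1P, KB1(L1363P)P against KB2P, KB1P against KP and KB2P against KP only 1 split, the real one, reached 5886, 5567, 5872 and 5226 genes, and the highest other counts were 774, 187, 134 and 1269. For sarcomatoid tumours against carcinosarcomas 2 splits reached 2540 genes, with a highest other count of 4868. Where only the real split reached the count, fewer than 5 of 100 splits did, so chance alone is an unlikely source of it. For sarcomatoid tumours against carcinosarcomas another split called 4868 genes, so chance was not excluded there. The splits do not separate genotype from histology or library series.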

How the results depend on the processing

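Large-scale transitions in adenocarcinomas, the sizes of lost calls, the threshold of 0.1, library series 5490, the removal of a near-identical profile, Fisher's exact test between histologies and the settings of high-level gain at Yap1 and Met were chosen only after the results were seen. Of 250 alternatives for the main comparisons 180 kept direction and side of the threshold, and for single genes 611 of 904 did. Few did so where histology was handled: with histology as a covariate 3 of 92 single-gene results did, 79 kept direction without passing and 10 changed direction, and in adenocarcinomas 4 of 92 did, 72 kept direction without passing and 16 changed direction. Of the 79 and 72, 12 and 33 were no smaller than in the main fit; the median ratio of sizes was 0.753 and 0.941 and that of SEs 1.25 and 1.77, so the lost calls do not by themselves show smaller differences. The 3 were Foxp1 in KB1P minus KP and Thoc1 and Atp5mpl in KB2P minus KP, and the 4 were Foxp1 and Cav2 in KB1P minus KP and Met and Cav1 in KB2P minus KP. Cav2, Cav1 and Met lie in 1 gained interval and are not separate results. High-level gain of Met was present in 2 of 6 KP adenocarcinomas and in 0 KB1P and 0 KB2P tumours. In series 5289 12 of 58 single-gene results kept direction and side of the threshold. Tumour numbers name tumours within a genotype, so no paired analysis between genotypes was made. Pairs of KB1(L1363P)P tumours that share a number were not tested as pairs, and no fit with library series as a block was run. Depth is unknown, and so is its effect on short segments.

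The altered share of KB1(L1363P)P minus KP was 1.56 in sarcomatoid tumours, 7.27 in adenocarcinomas and 2.08 as a difference of medians. KB1P minus KB2P was 1.76 in adenocarcinomas, 3.87 for medians and 0.0786 without a near-identical profile. In adenocarcinomas KB1(L1363P)P differed from KB1P by -15.1 and from KB2P by -13.3, no longer passing with 3 tumours. KB1P minus KP was 13.7 in series 5289, no longer passing with 3 KP tumours. Sarcomatoid minus carcinosarcoma was -4.24 in series 5289, 3.56 beyond 0.2 and 19.4 beyond 0.1.

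Breakpoints of KB1(L1363P)P minus KP were 1.2 in sarcomatoid tumours, 1.17 in adenocarcinomas and 2.5 for medians, and large-scale transitions 2.11, or 5.17 in adenocarcinomas. KB1(L1363P)P minus KB1P was -67.9 in adenocarcinomas, KB1P minus KP 35.1 in series 5289 and 69.0 in adenocarcinomas, none passing. KB1P minus KB2P passed at -73.0 without KB1PM and the conflicting label. The cause was not tested.

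Without each KB1(L1363P)P adenocarcinoma in turn, the altered share against KP, KB1P and KB2P ranged from -3.22 to 13.2, -25.6 to -9.15 and -23.8 to -7.39. Breakpoints against KP and KB2P ranged from -10.8 to 11.7 and -117.7 to -95.2, and large-scale transitions against KB1P and KB2P from -10.1 to -8.09 and -12.5 to -10.5. Only 2 tumours were left in these settings.

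Limma called 3 genes in KB1(L1363P)P minus KP in series 5289. KB1(L1363P)P minus KB1P had 0 genes by limma with histology as a covariate (4129 at unadjusted p under 0.05) and 0 in adenocarcinomas (1815). Fisher's exact test on all tumours, without regard to histology, called 12730. KB1(L1363P)P minus KB2P had 4 with the covariate and 0 by limma in adenocarcinomas (1851 at unadjusted p under 0.05; Fisher's exact test on all tumours called 8310). KB1P minus KP had 435 with the covariate, 852 in series 5289 and 450 in adenocarcinomas, and KB2P minus KP 25 with the covariate and 23 in adenocarcinomas. Sarcomatoid minus carcinosarcoma had 1630 on unsegmented ratios, 1270 after division by the SD, and 0 by Fisher's exact test, where limma had 10465 at unadjusted p under 0.05. Listed gains and losses called in KB1(L1363P)P minus KB2P were 21 beyond 0.2. The cause was not tested.

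Relative to the 20 nearest genes on each side, Brca1 was -0.0287 in KB1(L1363P)P minus KP, 0.0555 against KB1P and -0.0753 against KB2P, with KB1P minus KP -0.0842, KB2P minus KP 0.0466 and KB1P minus KB2P -0.131. Brca2 was 0.00318 in KB1(L1363P)P minus KB1P and 0.0796 against KB2P, with 0.0395 in KB1P minus KP, -0.0369 in KB2P minus KP and 0.0764 in KB1P minus KB2P. Trp53 was 0.0215 in KB1(L1363P)P minus KP, 0.0196 against KB1P and -0.0289 against KB2P, with 0.0504 in KB2P minus KP and -0.0485 in KB1P minus KB2P. In series 5289 Brca1, Brca2 and Trp53 were 0.0225, -0.0193 and 0.0558 in KB1(L1363P)P minus KB1P, and Brca2 and Trp53 0.192 and -0.131 in KB1P minus KP.

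With histology as a covariate and in adenocarcinomas, Yap1, Birc2, Birc3 and Tmem123 were -0.169 and -0.197 in KB1(L1363P)P minus KB1P and -0.181 and -0.194 in KB1(L1363P)P minus KB2P. Cdh1 was -0.0617 and -0.215 against KB1P, and Fanca -0.0262 and -0.194 against KB2P. In adenocarcinomas alone Met was -0.127 against KB1P, and Cdh1 -0.143, Vhl and Fancd2 0.0120, Foxp1 0.0539 and Arid1a -0.0702 against KB2P. Within series 5289 the gain at Yap1 differed by 56.1 points and that at Met by 24.1 points, no longer passing with fewer tumours.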

Other observations

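The comparisons in this part were chosen only after the results were seen, and none was tested. Among KB1(L1363P)P carcinosarcomas, the 2 tumours with high-level gain at Yap1 had 2% and 5% epithelial cells per the labels, and the 5 with gain at Met had 75% to 98%. The only sarcomatoid KB1P tumour, replicate 9, also carried the Yap1 gain, and its altered share of 0.356% was far below the KB1P mean. The only KB1P carcinosarcoma, replicate 5, had an altered share of 5.35% and neither gain.

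The spleens had 0 breakpoints and 0 large-scale transitions, and their largest segment value was 0.01 in size.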
